A study of Mus musculus with 6 samples.

How the data were processed

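Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and inserts sequencing adapters, in bone marrow B-cells of PEtg mice, the name the labels give the strain. Cells were separated by H2B-GFP, a histone tagged with green fluorescent protein that is diluted at each division, so that cells with much of it have divided little. The labels call the H2B-GFP high cells quiescent (n = 3 samples) and the H2B-GFP low cells proliferating (n = 3 samples). They do not say whether the samples came from separate mice, so p-values measure the spread between these samples, which may be partly technical. Per the labels' protocols, libraries were made with a commercial ATAC-seq kit and sequenced in a pair of runs per sample. The submitters' processing notes name Bowtie2, SAMtools, MACS2 and the mouse genome build mm10. Versions, settings, the handling of the transposase offset and the way reads were counted are not given in the sources used here.

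The authors deposited 1 signal value per sample for each of 97124 peaks, a single peak list shared by the 6 samples, with coordinates in mm10. Peaks were 200 to 13023 bp wide (median 547 bp), none lay on chromosome X or Y, and 4 lay on a sequence not placed in a chromosome. The values were not whole numbers, and the deposited signal summed to between 20904407 and 21518630 per sample. Low values lay on regular steps, the value of 1 read, and the size of the step changed smoothly with the mean of the peak. The product of the 6 steps lay between 0.998 and 1.0 in each decile of the peaks, so the authors' scaling depended on intensity and was centred over the samples. The purpose of that scaling is not given in the sources used here.

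The reads behind each value were estimated by following the step of each sample along peak strength in 4 rounds. Between 98.8% and 100.0% of the values of 1 to 1000 reads came out within 0.1 of a whole number. The estimated reads in peaks were 28332404, 14019462 and 18597151 in quiescent samples 1, 2 and 3, and 8053181, 31669957 and 48854668 in proliferating samples 1, 2 and 3. The median peak held 27 reads in proliferating sample 1 and 179 in proliferating sample 3. The value of 1 read was largest in quiescent sample 2 in the weakest decile (2.225, against 1.314 in proliferating sample 1) and in proliferating sample 1 in every other decile. In simulated reads scaled by the same curves, 99.7% of values were recovered exactly in each of the 6 samples over 97124 peaks.

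A test for raw counts had been chosen before the data were examined. As the deposited unit is a scaled signal, the planned substitute was used: limma 3.58.1 in R 4.3.3 with an intensity trend, on log2(value + 1), over the 87411 peaks whose mean lay above the lowest 10% of peaks. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, quiescent against proliferating, and understate the change of weak peaks. Values are given as mean ± SD of the deposited signal. Read recovery and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

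Peaks were assigned to the protein-coding gene they overlap, or else to the nearest within 100 kb, in a RefSeq gene table of GRCm38.p6, the assembly behind mm10. Of the 97124 peaks, 6364 had no such gene, and the others fell to 15430 genes. A nearest gene is a position and not a measured target. The table has no strand and no exons, so the start of a gene could not be told from its other end. The planned share of promoter peaks was therefore replaced by the share within 1 kb of either end of a gene, tested with Fisher's exact test, two-sided, with 3 kb as an alternative. The planned motif test and the correction for GC content need a genome sequence and were not run.

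The 13 gene lists used were fixed before the data were examined: cell cycle, quiescence and growth arrest, haematopoietic stem and progenitor, pro-B and pre-B, immature and mature B, IL-7 and JAK-STAT, AP-1 and immediate-early, interferon response, and adhesion and niche genes. The others were markers of myeloid cells, of T and NK cells, of erythroid cells and megakaryocytes, and of plasmacytoid dendritic and plasma cells. The peaks of each list were tested as a set with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, with adjustment over the 13 lists. The estimated form also rests on the few residual degrees of freedom of the design, so it has little power here. At an estimated correlation of 0.008, below the preset, the IL-7 and JAK-STAT list went from a camera adjusted p of 0.0792 to 0.401. Failing that form therefore cannot show that correlation between peaks removed a call. Camera compares a list with all other peaks. The limma test fry, chosen after seeing the data, tests whether a list moves one way on balance, without that comparison. Named peaks were chosen by a rule fixed before the data were examined. It takes, per direction, the 10 largest fold changes among peaks past the threshold with above-median signal, no overlap between the groups and a named gene, 1 peak per gene, and in each list the up to 4 genes with the lowest adjusted p. Some of the peaks chosen this way are not reported here.

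The replicate numbers of the labels are shared by both groups. The deviations of same-numbered samples from their group means correlated at 0.43, 0.29 and 0.21 for numbers 1, 2 and 3, each above the limit of 0.1 set for reading the numbers as pairs. Differently numbered samples gave -0.36 to 0.22, so number 3 did not stand out. Deviations within a group of 3 cancel out, so likeness between the samples numbered 1 raises the correlations among the others on average. Quiescent sample 2 with proliferating sample 3 gave 0.22, and quiescent sample 3 with proliferating sample 2 gave 0.15. The 3 values are therefore not separate evidence, and the pairing rests mainly on number 1. This pairing comes from the data and not from the labels, and the fit with the number as a block is printed where it changes a call or moves a count of changed peaks by over 1.5 times. Counts of genes are given without the block. They grow with the number of peaks assigned to each gene and were not set against other genes.

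The test was run on simulated reads for the 87411 peaks with 200 changed peaks. With reads that carry the intensity trend which the deposited scaling takes out, limma recovered 0 of 67 peaks changed 1.5-fold, 37 of 67 changed 2-fold and 65 of 66 changed 4-fold, with 2 false calls among 87111 unchanged peaks. In that simulation unchanged peaks were flat by construction, and all peaks and samples were drawn independently with the same spread. Its number of false calls therefore need not hold for the real samples. That simulation was added after a first one, whose reads lacked the trend, had given 391 false calls, with the unchanged peaks of the weakest decile shifted by 0.55 on the log2 scale. The calls thus assume that the trend taken out by the authors' scaling was technical. Alternatives covered the pseudocount, the filter, a minimum fold change, the block, each sample left out, sample weights and limma-voom on the recovered reads under 2 other scalings.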

Results

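Accessibility was compared between quiescent and proliferating bone marrow B-cells of PEtg mice, sorted by retention of the H2B-GFP label, with 3 samples per group. The design names this contrast, and the series title places it in a study of quiescence in pre-leukaemic stem cells. The deposited values had been brought to nearly equal totals, while the reads in peaks behind them ranged from 8053181 in proliferating sample 1 to 48854668 in proliferating sample 3. By their assigned protein-coding gene, 17.0% of the 97124 peaks lay within 1 kb of a gene end, 46.1% elsewhere in a gene body and 36.9% between genes.

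**Figure D1:**
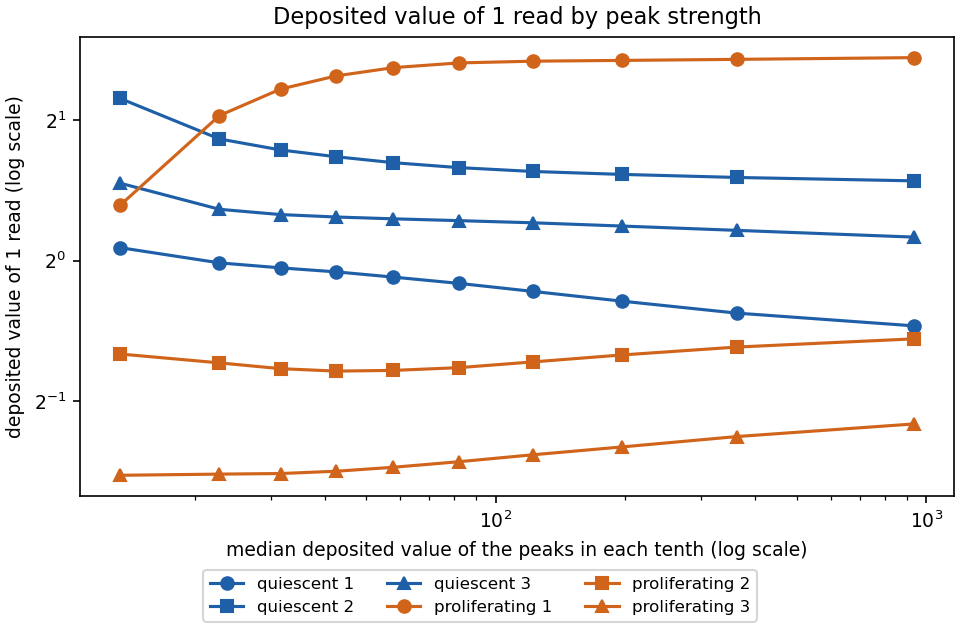
Deposited value of 1 read (y axis, log scale) against the median deposited value of each decile of the peaks (x axis, log scale), 1 line per sample. From the weakest to the strongest decile it went from 1.066 to 0.725 in quiescent sample 1 and from 1.314 to 2.721 in proliferating sample 1.

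Single peaks near genes of B-cell development rose or fell in quiescent cells, while neither list of B-cell genes passed as a set. A peak in the body of Ebf1, a transcription factor that specifies the B lineage, rose to 353 ± 76.1 in quiescent cells from 112 ± 9.08 in proliferating cells (log2 fold change 1.63 ± 0.20 SE, n = 3 each, limma adjusted p = 0.00773; chromosome 11, 44906334 to 44907478). A peak at the end of Ms4a1, which encodes the B-cell surface protein CD20, fell to 1065 ± 76.8 from 2066 ± 325 (-0.95 ± 0.14; chromosome 19, 11265679 to 11267469). A peak in Irf8, a transcription factor of B and myeloid cells, fell to 1460 ± 95.8 from 2568 ± 68.1 (-0.82 ± 0.10; chromosome 8, 120745138 to 120748978). Near Cdkn1a, which encodes the cell cycle inhibitor p21, signal was lower in quiescent cells, at 490 ± 81.4 against 1237 ± 110 (-1.34 ± 0.15; chromosome 17, 29071324 to 29074026, between genes, 16953 bp from the nearer end of Cdkn1a).

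In all, 5876 of 87411 tested peaks passed the threshold in limma, 3501 higher and 2375 lower in quiescent cells, so that 59.6% of the changed peaks were higher. Of these, 3990 changed by at least 1 on the log2 scale. The groups did not overlap at 26545 tested peaks (30.4%, against 10% by chance), all 5876 among them. With the replicate number as a block, 15999 peaks passed, 8885 higher and 7114 lower. The count rested on single libraries, since limma called 161 peaks without quiescent sample 2, 790 without proliferating sample 2, 1160 without proliferating sample 3 and 0 without quiescent sample 3. In that last case 16512 peaks had an unadjusted p under 0.05 and limma-voom on the recovered reads called 4910. When the recovered reads were scaled to their totals, the median of all tested peaks was -0.27, and 32.6% of 13246 changed peaks were higher in quiescent cells. With median-of-ratios scaling the share was 67.5% of 11687.

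Among changed peaks with above-median signal and a named gene, the largest rise lay in Bco2, which encodes a carotenoid-cleaving enzyme (chromosome 9, 50537180 to 50538033, in the gene body, 4093 bp from the nearer gene end). Its signal was 295 ± 29.0 in quiescent and 38.2 ± 19.96 in proliferating cells, a log2 fold change of 3.02 ± 0.33 (adjusted p = 0.006). The other peaks with the largest rises lay in or near Foxred2, Ssbp3, Otulinl, Lonrf2, Stmn3, Ankrd33b, Tnip3, Col6a6 and Ubac2, with log2 fold changes from 2.67 at Foxred2 to 2.42 at Ubac2. Among the same peaks the largest fall lay within Pcdhga12, in the clustered protocadherin genes (chromosome 18, 37787077 to 37787877), at 138 ± 54.2 in quiescent and 1012 ± 95.4 in proliferating cells (-2.93 ± 0.25, adjusted p = 0.00505). The others lay in or near Cdkal1, Afap1, Vps13c, Zcchc2, Vwa8, Mmp15, Strn, Taf4 and Prxl2a, from -2.90 at Cdkal1 to -2.35 at Prxl2a.

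Changed peaks lay away from gene ends. Among peaks higher in quiescent cells, 209 of 3501 (5.97%) lay within 1 kb of a gene end, against 18.6% of the other tested peaks (odds ratio 0.278, Fisher's exact test, two-sided, p = 1.08e-101). Among peaks lower in quiescent cells the share was 234 of 2375 (9.85% against 18.33%, odds ratio 0.487, Fisher's exact test, two-sided, p = 8.36e-30). With the replicate block the shares were 6.42% of 8885 and 11.5% of 7114 peaks. Neighbouring peaks are not independent, so these p-values are too small.

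Of the 13 gene lists, only the cell cycle list, genes of DNA replication and mitosis, passed as a set in camera, and it did not pass in fry (adjusted p = 0.0798). The median of its 142 peaks was -0.20 on the log2 scale (camera, adjusted p = 0.0184, and 0.0406 with the block), and it did not pass with an estimated correlation (adjusted p = 0.401), a form with little power in this design. Nor did the list pass without quiescent sample 1 (median -0.172, adjusted p = 0.0853) or without proliferating sample 2 (median -0.165, adjusted p = 0.0742). At the 62 peaks at gene ends the median was -0.29, with 50 below 0 (adjusted p = 3.65e-05, and adjusted p = 0.632 with an estimated correlation). All 15630 tested peaks at gene ends had a median of -0.08, a shift that camera did not take into account. Among 39 genes with a tested peak, 5 had only higher peaks past the threshold, 3 only lower peaks and 31 none. Adjusted over the list alone, 7 peaks were higher and 6 lower, against 5 and 6 over all peaks. Peaks fell near E2f8, a transcription factor of the cell cycle (-1.10 ± 0.17), and at the end of Rrm2, which encodes a subunit of ribonucleotide reductase (-1.74 ± 0.30), both lower in quiescent cells. A peak in Rrm1, the other subunit, rose (1.14 ± 0.20), as did a peak in Cdc6, a replication licensing factor (0.86 ± 0.18). The named Rrm2 peak was weak (25.8 ± 7.46 against 85.6 ± 1.21), and another weak peak at that gene's ends also fell (-1.70). The strongest peak at the ends of Rrm2 did not pass (855 ± 17.6 against 1017 ± 123, -0.24, limma adjusted p = 0.295). These further peaks were chosen after their values were seen.

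The quiescence and growth arrest list did not pass as a set (median 0.10, adjusted p = 0.127). Of 31 genes, 8 had only higher peaks past the threshold, 3 only lower peaks, 2 both and 18 none. Of their 375 tested peaks, 13 were higher and 4 lower adjusted over the list alone, and 16 and 5 adjusted over all peaks. Peaks rose in Foxo1, a transcription factor restrained by growth factor signalling (1.08 ± 0.17), and near Sesn3, a stress-response gene (1.27 ± 0.21), and fell near Cdkn1a and in Klf9 (-0.96 ± 0.15).

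The pro-B and pre-B list, genes of early bone marrow B-cell stages, had 9 of 30 genes with only higher peaks, 5 with only lower peaks, 6 with both and 10 with none (median 0.12, adjusted p = 0.105). These genes held 718 tested peaks, of which 28 were higher and 13 lower. Those shares were no larger than among all 87411 tested peaks (3501 higher and 2375 lower). Besides Ebf1 and Foxo1, a weak peak in Il2ra, the interleukin-2 receptor alpha chain, rose to 53.6 ± 4.48 from 10.1 ± 3.78 (2.36 ± 0.40). A stronger peak at the end of Il2ra, chosen after its values were seen, fell to 1054 ± 30.3 from 1590 ± 41.1 (-0.59, adjusted p = 0.0169). A strong peak near Bach2, a transcriptional repressor of B cells, fell to 1451 ± 59.1 from 2475 ± 327 (-0.76 ± 0.12), 66673 bp from the gene, while 5 peaks in the gene body rose past the threshold (0.74 to 2.26, chosen after their values were seen). In the immature and mature B list, 7 of 30 genes had only higher peaks, 6 only lower peaks, 1 both and 16 none (median 0.026, adjusted p = 0.421). The 4 named peaks of that list all fell, at Irf8 and Ms4a1, in Cd86, a costimulatory molecule (-1.08 ± 0.17), and near Cd83, an activation marker (-1.51 ± 0.30).

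Peaks of the IL-7 and JAK-STAT list, interleukin-7 signalling genes and STAT5 targets, had a median of 0.14 (adjusted p = 0.0792, and in fry 0.0455, or 0.135 with the block), with 6 of 25 genes only higher, 5 only lower, 1 both and 13 none. Peaks rose in Stat3 (1.62 ± 0.25) and near Pim1, a kinase gene induced by cytokines (1.56 ± 0.26), and fell near Socs2, an inhibitor of cytokine signalling (-1.62 ± 0.26). A peak near Myc, a driver of cell growth, fell to 102 ± 12.9 from 235 ± 3.80. In the AP-1 and immediate-early list (median 0.096, adjusted p = 0.105), 7 of 27 genes had only higher peaks, 3 only lower peaks, 3 both and 14 none. Without proliferating sample 3 the IL-7 list (median 0.164) and the AP-1 list (median 0.149) passed, both at an adjusted p of 0.05 after rounding, and with an estimated correlation neither did (adjusted p = 0.21 and 0.209). The named peaks near Klf6 (1.77 ± 0.24), Klf4 (1.14 ± 0.18), Nr4a1 (1.58 ± 0.27) and Ier3 (1.75 ± 0.31) rose. In the interferon response list (median 0.12, adjusted p = 0.105), 7 of 25 genes had only higher peaks, 1 only lower peaks and 17 none. Peaks rose in or near the interferon-induced genes Gbp4 (2.18 ± 0.26), Gbp3 (1.91 ± 0.36) and Ifitm3 (0.80 ± 0.16).

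The stem and progenitor list had 1 of 25 genes with only higher peaks, 2 with only lower peaks, 2 with both and 20 with none (median 0.02, adjusted p = 0.952). Peaks fell in Eya1 (-2.68 ± 0.27) and near Lmo2 (-0.96 ± 0.18), and rose in Erg (1.10 ± 0.21) and near Cd34, at a weak peak of 31.9 ± 2.23 against 6.98 ± 4.21. In the adhesion and niche list, 4 of 29 genes had only higher peaks, 8 only lower peaks, 4 both and 13 none (median -0.014, adjusted p = 0.957). Peaks near the integrin genes Itga4 (0.92 ± 0.14) and Itgal (1.24 ± 0.20) rose and a peak near Itga6 fell (-1.38 ± 0.21). A stronger peak at the end of Itga4, chosen after its values were seen, fell to 2682 ± 181 from 3796 ± 294 (-0.50, adjusted p = 0.0241). Sesn3, Lmo2, Erg, Cd86, Klf4 and Cd2 also had peaks past the threshold that changed against the named peak.

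Adjusted over the list alone, the pro-B and pre-B list had 23 higher and 10 lower peaks, against 28 and 13 over all peaks, and the immature and mature B list had 13 and 9 both ways. The IL-7 list had 20 and 9 adjusted over the list alone, against 16 and 7, the AP-1 list 24 and 8, against 19 and 6, and the interferon list 12 and 1, against 11 and 1. The stem and progenitor list had 1 and 2, against 4 and 4, and the adhesion list 16 and 17, against 12 and 17. In the adhesion list the median and the camera direction lay below 0 and the mean was 0.017. With the block, higher and lower peaks numbered 10 and 15 for cell cycle, 51 and 22 for quiescence, 28 and 29 for stem and progenitor, 72 and 52 for pro-B and 43 and 27 for mature B. They numbered 45 and 16 for IL-7, 34 and 18 for AP-1, 20 and 6 for interferon and 36 and 36 for adhesion.

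Markers of other cell types were measured beside these lists. Of the marker genes, 1 myeloid gene and 4 plasmacytoid dendritic and plasma cell genes also stand in another list. Myeloid markers had 9 of 21 genes with only higher peaks, 2 with only lower peaks and 10 with none (median 0.17, adjusted p = 0.0792), and passed without proliferating sample 3 (median 0.216, adjusted p of 0.05 after rounding, and 0.209 with an estimated correlation). In fry they passed (adjusted p = 0.0455, and 0.0716 with the block). At gene ends their median was 0.36 (adjusted p = 0.0205, and adjusted p = 0.377 with an estimated correlation). Peaks rose in Fcgr3 (1.04 ± 0.16), at the end of Csf1r, a receptor of monocytes and macrophages (1.06 ± 0.19), and near Ltf, and a peak near Csf3r fell (-1.71 ± 0.29). T and NK markers had a median of 0.004 over all peaks (adjusted p = 0.957) and 0.29 at gene ends (adjusted p = 0.0205, and adjusted p = 0.377 with an estimated correlation). Peaks rose in Cd247 (0.97 ± 0.16), at Klrb1c (1.17 ± 0.20) and near Ncr1 (1.94 ± 0.36), and one near Cd2 fell (-2.31 ± 0.43). Of 21 T and NK genes, 3 had only higher peaks, 2 both and 16 none. Among plasmacytoid dendritic and plasma cell markers (median 0.098, adjusted p = 0.105, and in fry 0.0455, or 0.135 with the block), 7 of 17 genes had only higher peaks, 2 only lower peaks, 1 both and 7 none. Peaks rose near Prdm1 (1.75 ± 0.19), Siglech (1.68 ± 0.23) and Jchain (1.13 ± 0.18), and the Irf8 peak, also named by this list, fell (-0.82 ± 0.10). Of 16 erythroid and megakaryocyte genes, none had only higher peaks past the threshold, 2 had only lower peaks and 14 had none (median 0.061, adjusted p = 0.957), with a peak near Vwf with a log2 fold change of -1.42 ± 0.36. Adjusted over the list alone, higher and lower peaks numbered 18 and 4 for myeloid markers (13 and 4 over all peaks), and 4 and 1 for T and NK markers (5 and 2). They numbered 29 and 10 for plasmacytoid dendritic and plasma cell markers (17 and 6), and 0 and 0 for erythroid and megakaryocyte markers (0 and 2). With the block they numbered 23 and 7 for myeloid, 10 and 14 for T and NK, 5 and 6 for erythroid and megakaryocyte, and 44 and 16 for plasmacytoid dendritic and plasma cell markers. For T and NK markers camera pointed down with a median and mean above 0, and for erythroid markers it pointed up with a mean of -0.013.

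**Figure D2:**
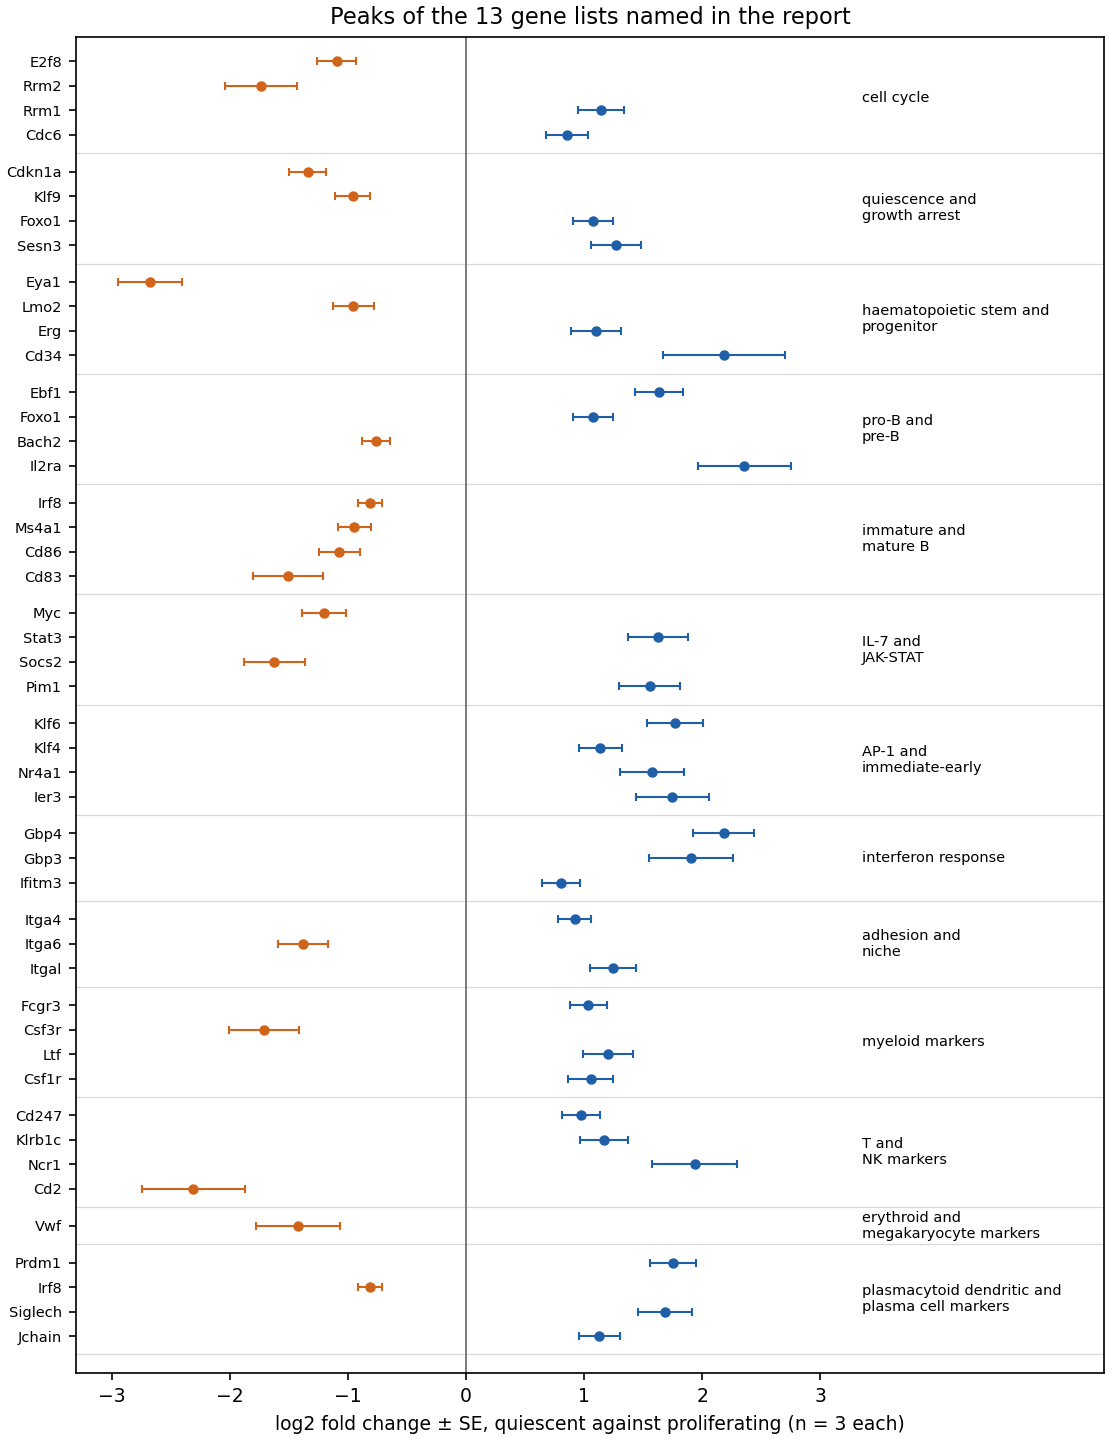
Log2 fold change ± SE of the peaks of the 13 gene lists whose genes are named in the text (n = 3 per group), filled where the adjusted p was under 0.05. All 4 named peaks of the immature and mature B list lay below 0, and all 4 of the AP-1 and immediate-early list lay above 0.

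**Figure D3:**
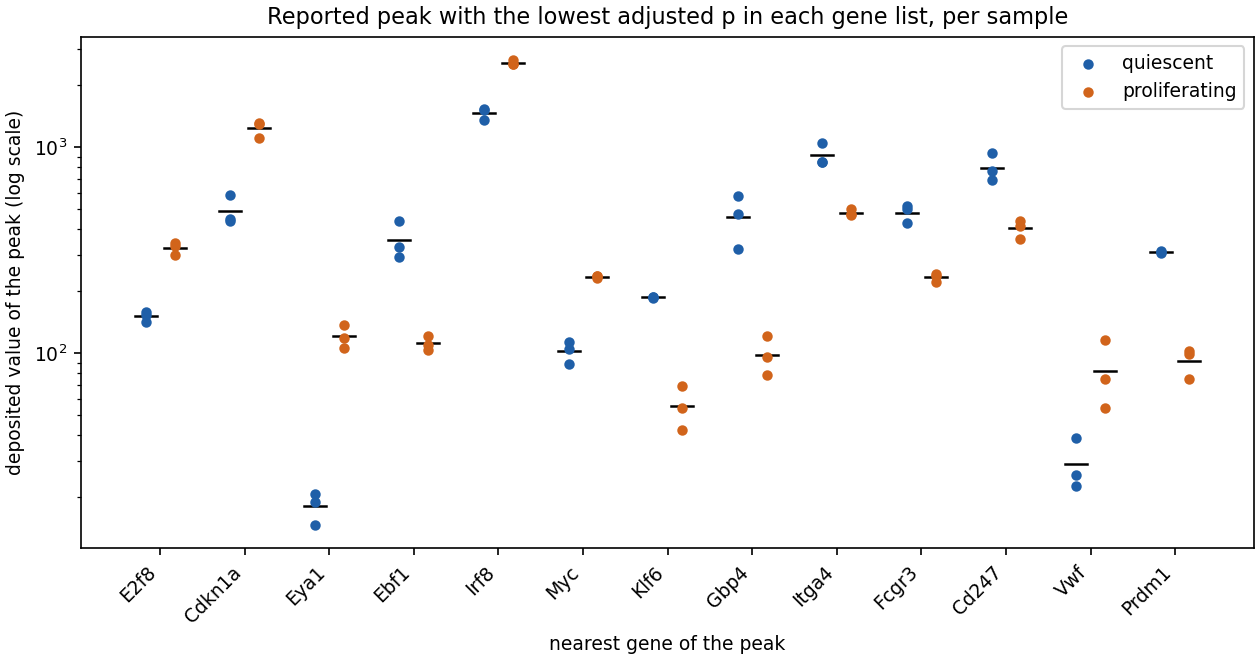
Deposited value (y axis, log scale) of the reported peak with the lowest adjusted p in each gene list, per sample, with the group mean as a line. At each of these peaks the 3 quiescent samples lay on one side of the 3 proliferating samples, as with Ebf1 at 353 ± 76.1 against 112 ± 9.08. The groups were apart at all 5876 peaks past the threshold, so this separation follows from the choice of peaks.

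Antigen receptor loci, chosen after their values were seen, held called peaks in different directions. Neighbouring peaks of a locus are not independent (estimated correlation 0.389 at the kappa locus), so the p-values of Fisher's test given here are too small. At the kappa light-chain locus (chromosome 6, 67555636 to 70726754), 35 of 296 peaks fell and 6 rose in quiescent cells (Fisher's exact test for falls against all other peaks, adjusted p = 2.83e-12), with the replicate block 71 fell and 19 rose, and with recovered reads scaled to their total 66 fell and 2 rose. That scaling favoured falls everywhere, with a median of -0.27 over all tested peaks and 8934 falls among 13246 changed peaks. Relative to the median of all peaks, the kappa median was -0.187 there. On deposited values without the block, the number that fell was 4 without quiescent sample 2, 0 without quiescent sample 3, 8 without proliferating sample 2 and 12 without proliferating sample 3. The median over all 296 was -0.21 (camera, adjusted p = 0.00308, and adjusted p = 0.67 with an estimated correlation), -0.096 without quiescent sample 1, -0.051 without proliferating sample 2 and -0.38 without proliferating sample 1. Per sample, the median deviation of the log2 value from the mean over samples at the kappa locus was -0.271, 0.041 and -0.059 in quiescent samples 1, 2 and 3, and -0.244, 0.487 and 0.117 in proliferating samples 1, 2 and 3. Each quiescent value lay below the proliferating value of the same number, by least for number 1. The groups overlapped, since proliferating sample 1 lay below quiescent samples 2 and 3. At the heavy-chain locus (chromosome 12, 113256204 to 116009954), 16 of 245 peaks rose and 4 fell (Fisher's exact test for rises, adjusted p = 0.149), with the block 45 rose and 8 fell, and with recovered reads 19 rose and 11 fell. On deposited values without the block, the number that rose was 0 without quiescent sample 2 or 3 and 2 without proliferating sample 2 or 3. The median was 0.34 (camera, adjusted p = 1.81e-05, and adjusted p = 0.393 with an estimated correlation). At the T-cell receptor beta locus (chromosome 6, 40891296 to 41558371), 8 of 34 peaks rose and none fell (Fisher's exact test, adjusted p = 0.000281), with the block 12 rose and 2 fell, and with recovered reads 7 rose and 3 fell. On deposited values without the block, the number that rose was 5 without quiescent sample 1, 0 without quiescent sample 2, quiescent sample 3 or proliferating sample 2, and 2 without proliferating sample 3, and 1 fell without proliferating sample 1. The median was 0.42 (camera, adjusted p = 0.00261, and adjusted p = 0.393 with an estimated correlation).

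**Figure D4:**
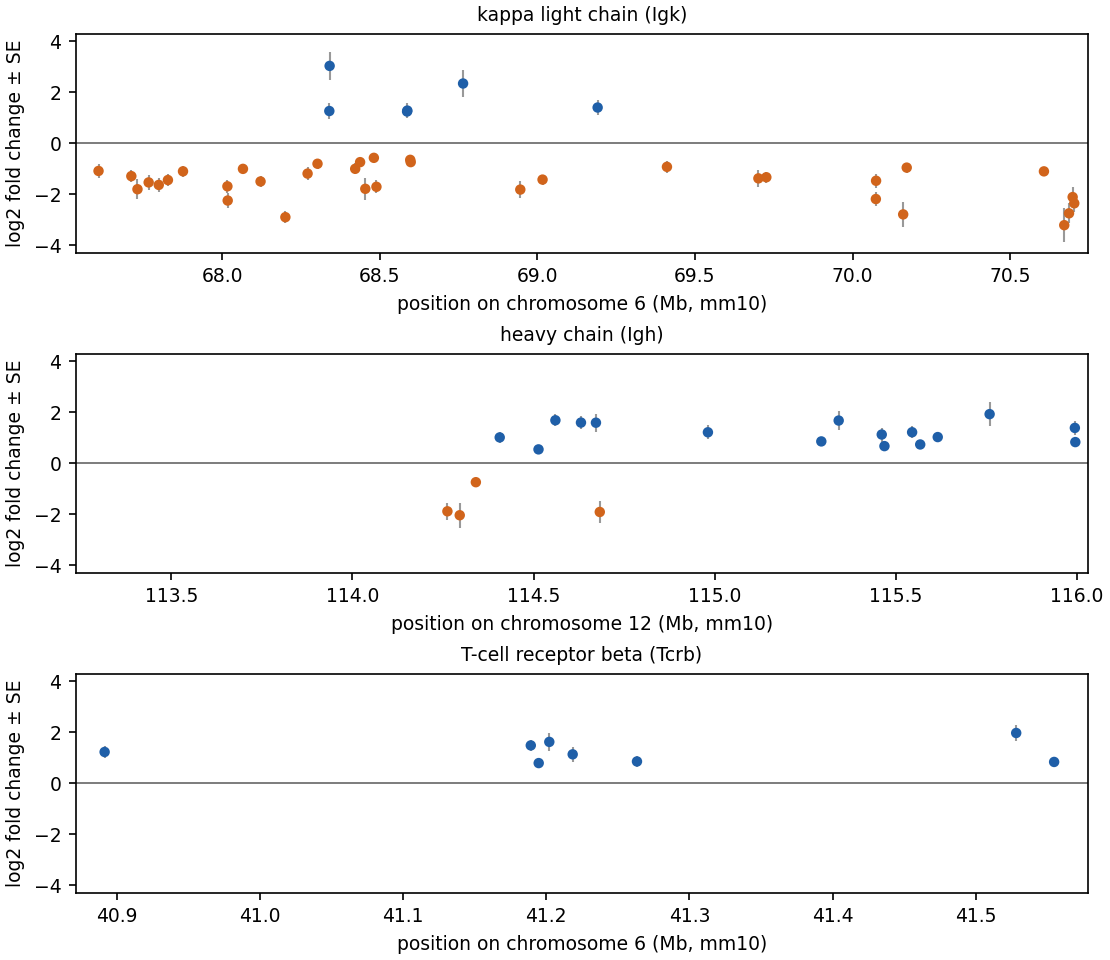
Log2 fold change ± SE of the peaks past the threshold along 3 antigen receptor loci (x axis, position in Mb), blue where higher and orange where lower in quiescent cells. The kappa locus holds 35 lower and 6 higher peaks, the heavy-chain locus 4 lower and 16 higher, and the T-cell receptor beta locus 8 higher.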

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

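The settings that use recovered reads, sample weights or fry, that leave out both samples numbered 1, or that join an estimated correlation to another setting were chosen after seeing the data. The number of changed peaks (5876) was 15999 with the replicate block, 19077 with sample quality weights, 13246 with recovered reads scaled to their total, 11687 with median-of-ratios scaling, 25006 with total scaling and quality weights, and 18201 without both samples numbered 1. It ranged from 0 to 8241 when each sample was left out in turn. There all 5876 peaks kept their direction and an unadjusted limma p under 0.05. The groups did not overlap at any of these peaks, so leaving out a sample could not turn a direction. The p-values come from the same samples that chose the peaks. A pseudocount of 0.1 gave 5672 and no filter 5652. The cause of these differences was not tested.

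The cell cycle list stayed below 0 throughout, from -0.30 to -0.17 over the samples left out (adjusted p 0.00103 to 0.0853). It lost its call without quiescent sample 1 (-0.172) or proliferating sample 2 (-0.165), and with an estimated correlation (median -0.196, adjusted p = 0.401). At the preset correlation it passed in camera without proliferating sample 3 (-0.189, adjusted p of 0.05 after rounding). It also passed there with recovered reads scaled to their total (-0.413 beside a shift of -0.27 of all peaks, adjusted p = 0.0299). Joined to an estimated correlation, these 2 settings gave an adjusted p of 0.477 and 0.628. With recovered reads scaled to their total, the IL-7 list passed (median -0.072 beside a shift of -0.27 of all peaks, adjusted p = 0.0411, and 0.628 with an estimated correlation), and the camera direction turned for the adhesion (-0.243), T and NK (-0.298) and erythroid (-0.323) lists. It turned for the adhesion list with the replicate block (-0.014), and without both samples numbered 1 for the adhesion (0.007), T and NK (-0.03) and erythroid (0.072) lists. With gene-end peaks alone it turned for the quiescence (-0.095), stem and progenitor (-0.069), pro-B (-0.034), mature B (-0.033) and T and NK (0.293) lists, and the T and NK and myeloid (0.359) lists passed (adjusted p = 0.0205 each, and 0.377 each with an estimated correlation). The median of all tested peaks at gene ends was -0.08, so a median below 0 there is not particular to these lists. With each sample left out, medians ranged from -0.029 to 0.041 for adhesion, -0.063 to 0.022 for T and NK, -0.017 to 0.119 for erythroid, 0.115 to 0.164 for IL-7, 0.069 to 0.149 for AP-1 and 0.098 to 0.216 for myeloid markers. The IL-7, AP-1 and myeloid lists passed without proliferating sample 3, each at an adjusted p of 0.05 after rounding, and none with an estimated correlation (adjusted p = 0.21, 0.209 and 0.209). These causes were not tested. In fry the cell cycle list did not pass (-0.196, adjusted p = 0.0798), and the IL-7 (0.136), myeloid (0.174) and plasmacytoid dendritic and plasma cell (0.098) lists did (adjusted p = 0.0455 each). With the block no list passed in fry, where the lowest adjusted p was 0.0716. The direction in fry was up for the adhesion (-0.014) and T and NK (0.004) lists, and down for the erythroid list (0.061) with the block. In camera the block changed no other list or gene-end call. Shares of peaks at gene ends could not be computed without quiescent sample 3, where no peak passed; over the other samples left out they ranged from 5.35 to 8.86% among higher and 6.14 to 13.71% among lower peaks.

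Of 980 tests of the 70 named peaks under other settings, 774 kept their side of the threshold, 194 fell short of it, 12 passed it newly and 0 reversed. The groups did not overlap at the named peaks, so the settings that leave samples out could not reverse them. The planned count tests, GC offsets and motif tests were not run. Depth differed, with the fewest reads in peaks in proliferating sample 1 (8053181) and the most peaks without a read in quiescent sample 2 (1424).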

Other observations

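All tests on antigen receptor loci and on recovered reads concern patterns noticed in these data, and the tests of chance for the number of peaks, of proliferating sample 1, of background and of a later B-cell stage were chosen after the result was seen. The other receptor loci held few called peaks. At the lambda light-chain locus none of 18 peaks passed the threshold without the block, and 4 rose and 1 fell with it, with a median of 0.43 (camera, adjusted p = 0.0303, and adjusted p = 0.393 with an estimated correlation). At the T-cell receptor alpha and delta locus 1 of 19 peaks fell, and 5 rose and 1 fell with the block (median 0.51, adjusted p = 0.307), and at the gamma locus 1 of 10 rose (median 0.095, adjusted p = 0.47). Within the kappa locus the peak with the lowest adjusted p (chromosome 6, 68200388 to 68200770) was at 71.1 ± 14.1 in quiescent and 540 ± 130 in proliferating cells (n = 3 each, limma, adjusted p = 0.00463).

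The real grouping gave 5876 changed peaks and the highest of the other splits of the 6 samples gave 0, so 1 of the 10 splits reached the real count. With the block, the real split gave 15999 peaks and the other splits that part all 3 pairs gave at most 0. For the gene lists, 6 of the 10 splits gave at least 1 list past the threshold and the highest gave 2. A design of 3 samples against 3 makes too few splits for a share under 0.05.

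When recovered reads were scaled to their totals, weak peaks lay lower and strong peaks higher in quiescent samples, with medians of -0.59 in the weakest and 0.07 in the strongest decile. After all libraries were thinned to 7957084 reads the gap between these medians was -0.629, beside -0.66 before. Thinning keeps the peak list and each peak's expected share of reads, so it cannot decide on unequal depth as the cause. A gap of -0.67 without proliferating sample 1 argues against that sample alone as the cause. A difference in background between the sorted fractions cannot be told apart from biology. The exact permutation test of the value of 1 read (two-sided p = 0.1, the smallest that 3 against 3 allow) restates the trend and does not bear on background. Over tested peaks, the value of 1 read in the weakest relative to the strongest decile was 1.37, 1.24 and 1.15 in quiescent samples and 0.74, 0.89 and 0.78 in proliferating samples. A change in overall accessibility with quiescence stays open, and the authors' scaling takes out the whole trend.

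The median of the kappa locus lay below 0, and those of the heavy-chain and T-cell receptor beta loci above 0. None of these loci passed with an estimated correlation, a form with little power in this design (camera, adjusted p = 0.67, 0.393 and 0.393, and 0.636 for each with the block). T and NK markers at gene ends also lay higher in quiescent samples (median 0.293, 18 of 21 above 0, adjusted p = 0.0205, and 0.377 with an estimated correlation), but not over all 136 of their peaks (median 0.004, adjusted p = 0.957). Myeloid markers at gene ends lay higher as well (median 0.359). Neighbouring kappa peaks differed more than in most other stretches (percentile 99.3 of 1000). This cannot decide on loss of DNA over the kappa locus, since a loss shared by neighbours leaves their differences unchanged. The other stretches were also not matched for signal. Of called kappa peaks, 43.9% overlapped no annotated segment, against 56.8% of all kappa peaks, a difference that was not tested. Overlap alone cannot show whether reads shared between similar V segments contribute to a difference between the groups. A later B-cell stage in the proliferating samples cannot be told apart from these, since the immature and mature B list did not pass as a set (adjusted p = 0.421).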
